A study of Homo sapiens with 2 samples.

How the data were processed

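Small RNA libraries were made from total RNA of MDA-MB-231 cells with a TruSeq small RNA kit and sequenced on an Illumina NextSeq instrument, with 1 library per condition. The labels name the partner cells both as mature adipocytes and as mouse pre-adipocytes; the growth notes describe differentiation, and differentiated cells are assumed here. The submitters' processing notes name Bowtie 1.1.1 and the GRCh38 build. Adapter trimming, read filters, strand handling, the treatment of reads that match several loci and the counting tool were not given in the sources used here. Each could change single values, above all for paralogs, for hairpins on opposite strands and for microRNAs with several genomic copies.

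The authors deposited a workbook whose 4 sheets used here hold a summary of calls, the microRNAs found in both libraries, those found only alone and those found only in co-culture. The expression columns the authors deposited hold signal in the form of DESeq size-factor-normalized read counts. Per the file headers, the other columns are FoldChange, a ratio of co-culture to alone, log2FoldChange, its log2 value, and the p-value with its adjusted p-value. The columns are numbered 1 and 2. They were matched to alone and co-culture through the sheets for entries found in 1 library only and through the summary sheet, which names control and treatment. Every value in a column was a whole multiple, within a tolerance of 1e-06, of that column's smallest value, 0.80855 in the alone library and 1.23677 in the co-culture library. Dividing by this step gave the counts analysed. The analysis plan had expected counts in the files and allowed for normalized values. Counts recovered in this way are called counts throughout, and a column's sum covers the listed microRNAs only and is not the sequencing depth.

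Of 190 rows in the sheet of shared microRNAs, 2 were blank, so 188 were used. The authors' summary counts 49 up calls over the 190, against 47 in the rows used, while the 49 down and 92 neutral calls were all held. The higher class and the listed totals here may therefore lack 2 entries that the authors called up. The 29 entries found only in co-culture and the 43 found only alone were taken as 0 in the other library, since entries with 1 count are listed. Each library was scaled to its listed total, as counts per 1000000 listed counts. Log2 ratios of co-culture to alone used a prior count of 0.5 per library. A microRNA was classed by size alone: at least 2-fold higher or lower among those with a mean count of at least 10. With 1 library per group no test was run and no p-value computed. Levels carry exact Poisson intervals, ratios of counts exact conditional binomial intervals, and shares Wilson intervals, all at 95% and all for counting error only. PCR copies were not told apart by molecular identifiers, so the real error is larger. Ratios against a count of 0 are bounds, computed against a floor of 3 counts in that library, and ratios resting on 1 to 3 counts are given with their interval.

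Before the data were examined, 20 lists of microRNAs, 15 pairs of microRNAs on opposite strands and the rule for naming microRNAs were fixed. The rule takes the 2 microRNAs of the title, the 12 largest rises and 12 largest falls at a mean count of at least 50, the 10 most abundant, the 5 with the highest counts among those in each library only, up to 4 of the most abundant members of each list, and opposite-strand pairs with both partners listed. MiR-3184-3p, miR-181a-3p, miR-24-3p, miR-27a-5p, miR-27b-5p, miR-106b-3p, miR-196b-5p, let-7b-5p, let-7b-3p, miR-148a-3p, miR-365a-3p, miR-30e-3p and miR-143-3p fall outside the rule. They were added after their values were seen. The lists are the let-7, miR-200, miR-17-92, miR-181, miR-30, miR-29, miR-15/16, miR-23/27/24 and miR-34 families or clusters, microRNAs described as promoting or restraining breast cancer, inflammation-responsive, adipocyte-associated, fibroblast, blood and immune, and muscle, liver and neural microRNAs, the imprinted chromosome 14 and the primate-specific chromosome 19 clusters, entries that resemble rRNA or tRNA, and the title pair. List medians carry an interval from 2000 Poisson redraws of the counts. Each median was ranked among 10000 random sets of the same size, matched in 10 bins of mean count, which describes these libraries and does not test the conditions.

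Hairpin positions and host genes were taken from GENCODE release 29 on GRCh38 by name, and 259 of the 260 entries matched a hairpin. A microRNA with several hairpins cannot be assigned to any one of them. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9. The calls were tested on simulated data made by redrawing the counts 20 times with known differences. All 395 true 4-fold differences were called, against 2.5% of 200 true 1.5-fold differences and 0.793% of 1514 unchanged microRNAs, and 95.7% to 97.0% of intervals covered the true ratio. The simulation held counting error only and no variation between cultures. Alternatives tried were 4 other scalings, the log2 ratios the authors deposited, no count limit or a mean count of at least 50, a prior count of 5, entries with the same counts taken once, only microRNAs in both libraries, and stricter limits for detection in 1 library. The trimmed mean of M values used trims of 30% and 5%.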

Results

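Small RNA was sequenced from MDA-MB-231, an established human breast cancer cell line of mesenchymal character, grown alone or for 5 days beside differentiated 3T3-L1 cells, a mouse line used as a model of fat cells. The cell types shared medium but were kept apart by a porous membrane. Each condition has 1 library, so no replicate error exists and no test of the condition was possible. All intervals are at 95% and cover counting error only. The tables analysed list 260 human mature microRNAs. Their counts sum to 171149 in the alone library and 119612 in the co-culture library, which is 1.43 times fewer. A floor of 3 counts equals 17.5 counts per 1000000 listed counts (CPM) in the alone library and 25.1 CPM in the co-culture library. Higher and lower refer below to a difference of at least 2-fold among the 111 microRNAs with a mean count of at least 10, which hold 99.7% of the counts in each library.

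The comparison asks which microRNAs of the breast cancer cells differed after co-culture with adipocytes. MiR-27b-3p, miR-31-5p, miR-181a-5p and miR-210-3p were among those at higher levels beside adipocytes, and let-7i-5p, let-7f-5p, miR-146b-5p and miR-423-3p among those at lower levels. Of the 111 microRNAs, 22 were higher in co-culture, 31 were lower and 58 lay within 2-fold. The whole counting interval lay beyond 2-fold for 17 of the higher and 23 of the lower microRNAs. Over the 110 of these that were listed in both libraries, the median log2 ratio of co-culture to alone was −0.24 (−0.30 to −0.09). It can be set beside the family medians below, which are also ranked among matched random sets. Scaling to the upper quartile moved every log2 ratio up by 0.62 and turned the balance to 37 higher and 22 lower, with a median of 0.39. Scaling to the median of ratios moved them by 0.14 and gave 24 higher and 30 lower.

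The most abundant microRNA had a similar share in both libraries. MiR-10b-5p, encoded in the HOXD3 intron (chromosome 2, 176150303 to 176150412, plus strand, GRCh38) and linked to breast cancer cell invasion, took 32.9% of the listed counts alone and 33.6% in co-culture. Its paralog miR-10a-5p had a ratio of co-culture to alone of 1.05 (1.03 to 1.07). Reads could be shared between these close paralogs, and their summed level had a ratio of 1.03 (1.02 to 1.04). MiR-21-5p, often abundant in tumours, was at 33737 CPM alone and 49627 CPM in co-culture, a ratio of 1.47 (1.42 to 1.53) that passed 2-fold only under upper-quartile scaling. MiR-92a-3p of the proliferation-linked miR-17-92 cluster was at 127731 CPM alone and 72894 CPM in co-culture, a ratio of 0.571 (0.557 to 0.585). The ratios of let-7c-5p (0.858), miR-151a-3p (0.789) and miR-191-5p (1.21) lay within 2-fold, and under upper-quartile scaling the first and second of these were above 1. The 10 most abundant entries of each library, ranked within that library, took 77.1% of the counts alone and 78.1% in co-culture.

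**Figure D1:**
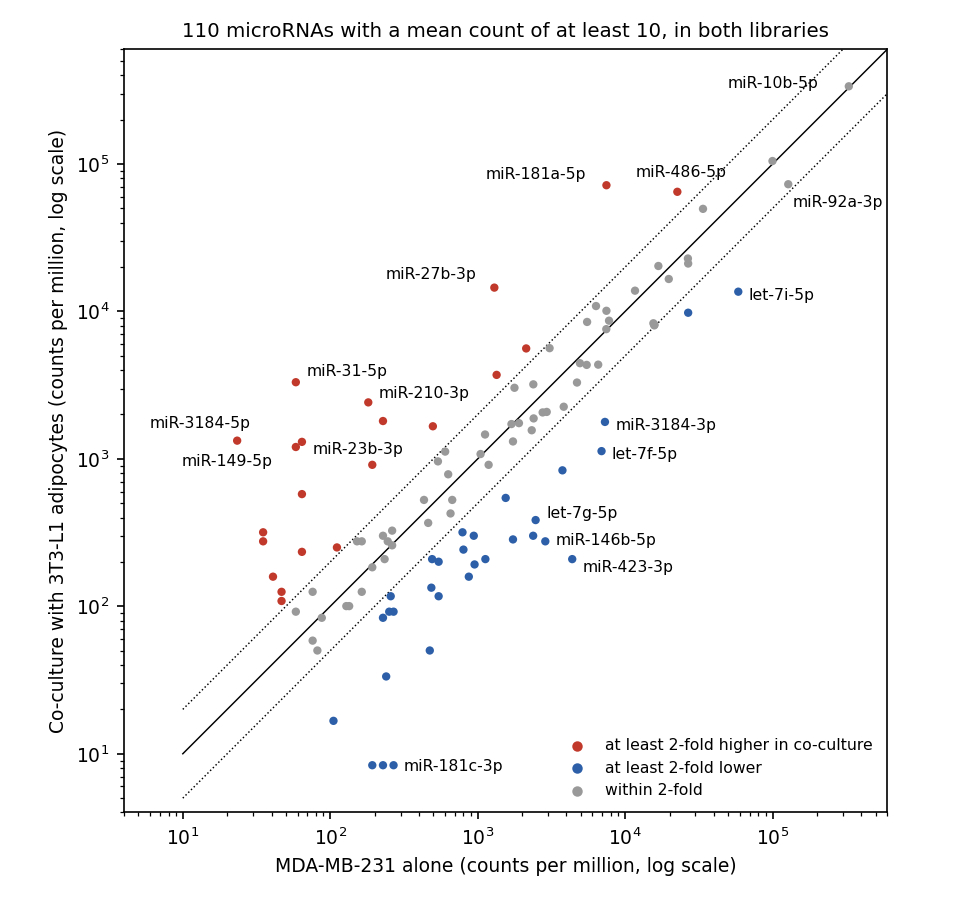
Levels of the 110 microRNAs with a mean count of at least 10 that were listed in both libraries, in CPM on log axes, for MDA-MB-231 alone (horizontal) and in co-culture (vertical), 1 library each. The solid line marks equal levels and the dotted lines 2-fold; miR-10b-5p lies near equality, while miR-181a-5p lies 9.61-fold above it and let-7i-5p 4.30-fold below it.

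Among microRNAs with a mean count of at least 50, the highest ratios of co-culture to alone belonged to both scarce and abundant species. MiR-31-5p, described as restraining breast cancer metastasis (chromosome 9, 21512115 to 21512185, minus strand, no host gene on that strand), had 10 counts alone and 396 in co-culture, 56.7-fold higher (30.5 to 119). MiR-149-5p, from an intron of GPC1, was 20.6-fold higher (10.9 to 43.9). MiR-210-3p, the best known hypoxia-induced microRNA (chromosome 11, 568089 to 568198, minus strand, intron of MIR210HG), was at 181 CPM alone and 2416 CPM in co-culture, 13.3-fold higher (9.193 to 19.998). MiR-181a-5p, with hairpins on chromosomes 1 and 9, had 1278 counts alone and 8584 in co-culture and was 9.61-fold higher (9.06 to 10.2). MiR-151a-5p, from an intron of PTK2, was 7.92-fold higher (5.61 to 11.5). MiR-1273g-3p was 4.73-fold higher (3.18 to 7.21) and miR-486-5p, abundant in red blood cells, 2.87-fold higher (2.76 to 2.98).

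Members of the miR-23/27/24 clusters differed in direction. MiR-23b-3p (chromosome 9, 95085208 to 95085304) and miR-27b-3p (95085445 to 95085541), both from an intron of C9orf3, were 20.3-fold (11.03 to 41.5) and 11.2-fold (9.72 to 12.9) higher in co-culture. Their chromosome 19 counterpart miR-27a-3p was 5.48-fold lower (3.39 to 9.36), while miR-23a-3p had a ratio of 0.797 (0.538 to 1.17), above 1 under upper-quartile scaling, and miR-24-3p, made at both loci, one of 0.986 (0.603 to 1.59). The paralogs are nearly identical in sequence and reads could be assigned to either. Of the opposite arms of the miR-27 hairpins, miR-27a-5p was 9.43-fold lower (4.15 to 26.5) and miR-27b-5p had 7 counts alone and 2 in co-culture. Summed, miR-23a-3p and miR-23b-3p were 3.18-fold higher (2.47 to 4.12), and miR-27a-3p and miR-27b-3p 6.76-fold higher (6.04 to 7.59). Of the 5 members, 2 were higher, 1 was lower and 2 lay within 2-fold, with a median of −0.01 that changed sign under other scalings.

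The let-7 family, repressors of RAS and HMGA2 transcripts, was lower in co-culture. Of its 9 members, 5 were lower, 4 lay within 2-fold and none was higher. The family median was −2.10 (−2.18 to −2.02), at the 0.04 percentile of 10000 random sets of the same size and matched abundance. It lay between −2.10 and −1.48 under every scaling tried, and 5 members stayed lower under each. Let-7i-5p (chromosome 12, 62603686 to 62603769, plus strand) was the most abundant member alone, with 10019 counts against 1628 in co-culture, 4.30-fold lower (4.08 to 4.54). Let-7f-5p was 6.13-fold lower (5.13 to 7.38), let-7g-5p 6.43-fold (4.73 to 8.91), let-7e-5p 7.90-fold (5.61 to 11.4) and miR-98-5p 6.10-fold (4.27 to 8.98). Let-7a-5p was 1.95-fold lower (1.81 to 2.10), short of the 2-fold limit. Members differ by few bases, and the summed family was 2.22-fold lower (2.16 to 2.28), or 1.44-fold lower under upper-quartile scaling. Without let-7i-5p the sum was 1.51-fold lower (1.46 to 1.56), and its ratio was 1.02 under upper-quartile scaling. Let-7b-5p had a ratio of 1.83 (1.63 to 2.06), past 2-fold under median-of-ratios and upper-quartile scaling.

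Other microRNAs at lower levels in co-culture lay outside that family. MiR-146b-5p, induced by NF-kappaB and acting as its brake (chromosome 10, 102436512 to 102436584, plus strand), had 492 counts alone and 33 in co-culture, 10.4-fold lower (7.32 to 15.3). MiR-196a-5p, encoded among the HOX genes, was 5.40-fold lower (3.55 to 8.54), and 4.08-fold (3.00 to 5.64) when summed with its paralog miR-196b-5p. MiR-409-3p of the imprinted chromosome 14 cluster was 4.95-fold lower (3.19 to 8.03), miR-4792 4.64-fold (2.63 to 8.82) and miR-125b-1-3p 4.49-fold (3.64 to 5.61). MiR-125b-5p, pooled over the hairpin of the last and another on chromosome 21, had a ratio of 0.663 (0.597 to 0.736), which was above 1 under upper-quartile scaling.

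**Figure D2:**
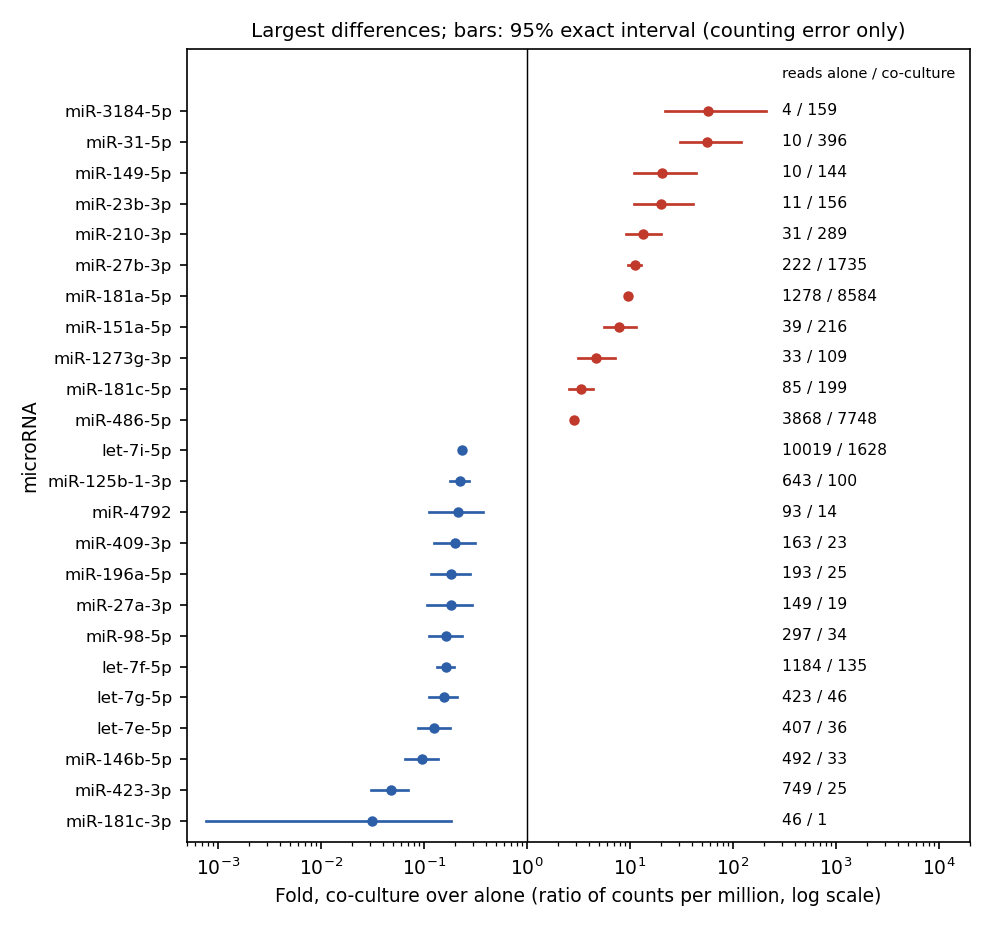
Ratios of co-culture to alone, on a log axis, for the microRNAs with the largest differences at a mean count of at least 50 and for miR-181c-3p, which the series title names; bars are 95% exact intervals of counting error and the figures at right are counts in the 2 libraries. MiR-1973 is not drawn, as it has no counts alone; of the ratios drawn, miR-3184-5p stands highest at 56.9-fold, resting on 4 counts alone, and miR-181c-3p lowest, resting on 1 count in co-culture.

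The series title names miR-3184-5p and miR-181c-3p, in a study that holds these same libraries, so their difference here is not taken as independent evidence; how they were chosen was not given in the sources used here. MiR-3184-5p had 4 counts alone and 159 in co-culture, 56.9-fold higher (21.8 to 211). MiR-181c-3p had 46 counts alone and 1 in co-culture, a ratio of alone to co-culture of 32.1 (5.49 to 1297). It is 1 arm of a hairpin in an intron of NANOS3 (chromosome 19, 13874699 to 13874808, plus strand). The opposite arm, miR-181c-5p, had 85 counts alone and 199 in co-culture, 3.35-fold higher (2.59 to 4.37). The pair's median log2 ratio was 0.61, at the 66.4 percentile of matched random sets, since 1 of the 2 was higher and 1 lower.

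The MIR3184 hairpin (chromosome 17, 30117086 to 30117160, minus strand) lies wholly within the span of MIR423 (30117079 to 30117172, plus strand, in an exon of NSRP1). MiR-3184-5p pairs in position with miR-423-3p, whose counts went the other way, from 749 alone to 25 in co-culture, 20.9-fold lower (14.1 to 32.6). MiR-3184-5p made up 0.531% of the pair's counts alone (Wilson interval 0.207% to 1.36%) and 86.4% in co-culture (80.7% to 90.6%). Summed without regard to strand, the pair had 753 counts alone and 184 in co-culture, 2.86-fold lower (2.43 to 3.38). This reverses the direction seen for miR-3184-5p by itself. Under upper-quartile scaling the sum was 1.86-fold lower. The strand handling behind the counts was not given in the sources used here. On the other arm, miR-3184-3p had 1249 counts alone and 213 in co-culture, 4.10-fold lower (3.54 to 4.76), while miR-423-5p was not among the entries analysed.

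**Figure D3:**
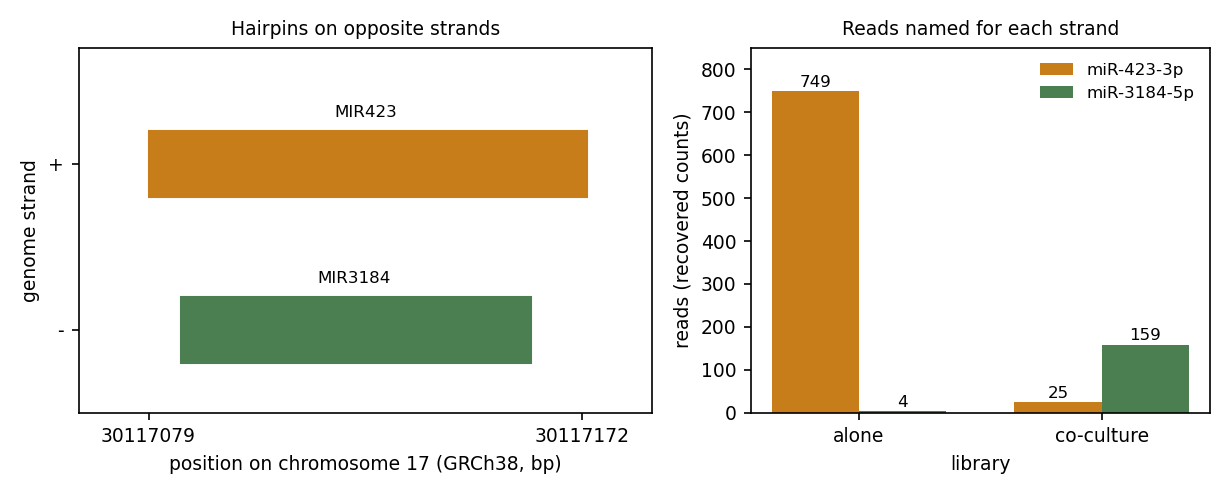
Left, the MIR423 and MIR3184 hairpins on opposite strands of chromosome 17, drawn to scale in base pairs. Right, counts named miR-423-3p or miR-3184-5p in each library; the name that holds most of the counts changes from miR-423-3p alone (749 against 4) to miR-3184-5p in co-culture (159 against 25).

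In the miR-181 family, 3 of 6 tested members were higher, 2 were lower and 1 lay within 2-fold. This list holds 3p as well as 5p arms, whereas the let-7 and miR-30 lists hold 5p arms only. The higher members were the 5p arms of miR-181a, miR-181b (2.63-fold, 2.31 to 3.00) and miR-181c. The lower members were miR-181c-3p and miR-181a-3p, the latter 2.35-fold lower (1.49 to 3.83) but within 2-fold under upper-quartile scaling. MiR-181d-5p had a ratio of 0.652 (0.458 to 0.915), which was above 1 under upper-quartile scaling. The summed family was 6.90-fold higher (6.57 to 7.25), mostly miR-181a-5p, and the median over both arms was 0.39, at the 80.5 percentile. Among the 5p arms only miR-181d-5p was not higher.

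Among the remaining families, 2 of 4 miR-30 members were lower and none was higher, with a median of −1.01 at the 17.0 percentile. MiR-30d-5p, the most abundant of them, was 2.73-fold lower (2.56 to 2.92), within 2-fold under upper-quartile scaling. All 7 tested members of the list of miR-17-92 and its paralogs lay within 2-fold. Their median of −0.33 (27.3 percentile) became 0.29 under upper-quartile scaling, where 2 members were higher. MiR-106b-3p, an arm of a paralog that the list leaves out, was 2.48-fold lower (1.72 to 3.66), within 2-fold under upper-quartile scaling. Of the miR-29 family, repressors of extracellular matrix genes, 1 of 2 was higher, miR-29b-3p at 2.26-fold (1.23 to 4.25), and the median was 0.59 (77.3 percentile). The 4 miR-15/16 members, repressors of the cell cycle, had a median of 0.13 (59.1 percentile) and lay within 2-fold, although 1 was higher under upper-quartile scaling. The 2 tested members of the p53-responsive miR-34 family had a median of −0.02 (52.2 percentile) whose sign changed with the scaling. No member of the epithelial miR-200 family or of the primate-specific chromosome 19 cluster was among the entries analysed.

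**Figure D4:**
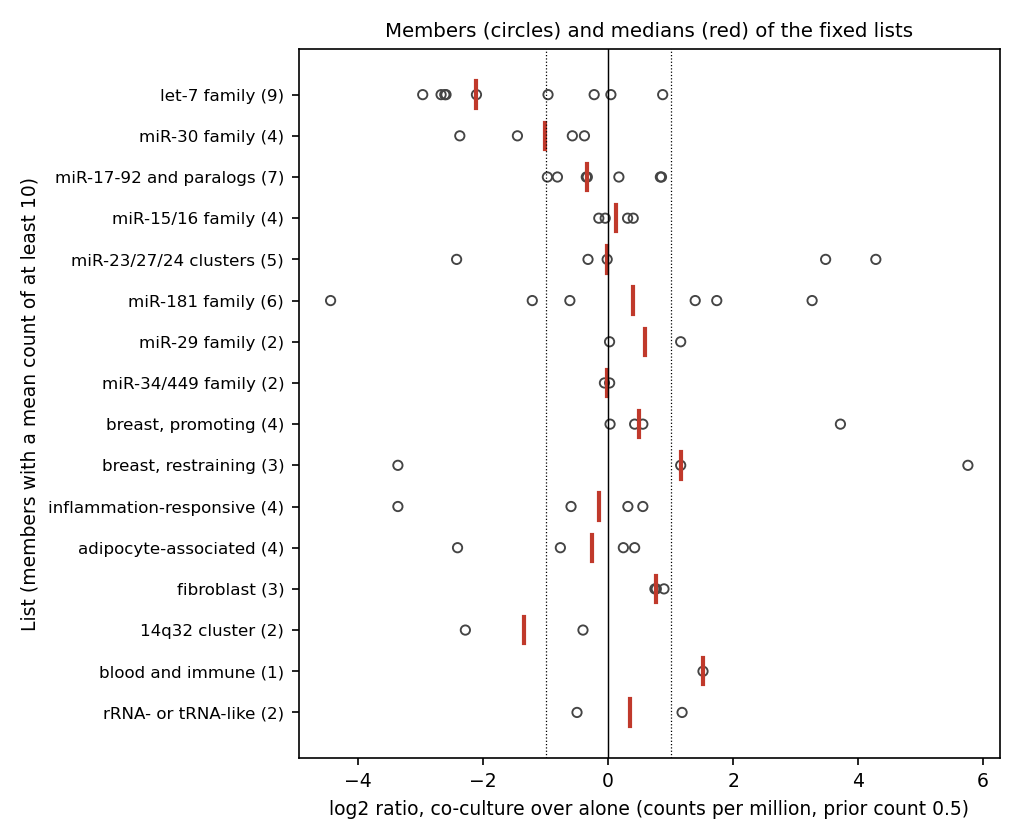
Log2 ratios of co-culture to alone for the tested members (circles) and median (red bar) of each fixed list, with the number of tested members in brackets and 2-fold marked by dotted lines. The let-7 median lies at −2.10 under the scaling plotted; the medians of 5 lists (miR-17-92, miR-23/27/24, miR-34, inflammation-responsive and adipocyte-associated) changed sign under another scaling.

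Few members of the lists fixed by described function could be tested. Of 4 tested microRNAs described as promoting breast cancer, 1 was higher (miR-210-3p) and 3 lay within 2-fold, with a median of 0.49 (82.4 percentile). Upper-quartile scaling made 3 of the 4 higher. Of 3 described as restraining it, 2 were higher (miR-31-5p and miR-29b-3p) and 1 was lower (miR-146b-5p), with a median of 1.16 (87.7 percentile). With the fourth listed member, miR-193b-3p, the median was 3.27, which depends on the prior count because miR-193b-3p had no counts alone, or 1.95 with miR-193b-3p at its bound against the floor of 3 counts. The inflammation-responsive list had 1 of 4 lower, miR-146b-5p, and a median of −0.14 (61.6 percentile) that changed sign under upper-quartile scaling. MiR-146b-5p is the lower member of both this and the restraining list, so these counts are not separate evidence.

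MicroRNAs described for adipocytes, fibroblasts and other sources were measured the same way, under human names that do not mark mouse cells. The adipocyte-associated list had 1 of 4 lower, miR-196a-5p, and none higher, with a median of −0.26 (39.8 percentile) whose sign changed under upper-quartile scaling. MiR-378a-3p and miR-103a-3p of that list had ratios of 1.19 (1.11 to 1.27) and 1.34 (1.17 to 1.55), the latter past 2-fold under upper-quartile scaling. All 3 tested fibroblast microRNAs lay within 2-fold but above 1 under every scaling, with a median of 0.77 (88.2 percentile), and all 3 passed 2-fold under upper-quartile scaling, as did miR-199b-3p under the median of ratios. In the imprinted chromosome 14 cluster 1 of 2 was lower, with a median of −1.34 (22.8 percentile). Of the blood and immune markers only miR-486-5p could be tested, with a log2 ratio of 1.52. The list of muscle, liver and neural markers had 1 listed member, miR-219a-5p, with 1 count alone and 2 in co-culture. The tested entries that resemble rRNA or tRNA had 1 of 2 higher, miR-4454 with 8 counts alone and 13 in co-culture, and a median of 0.34 (74.4 percentile), or 1.18 with miR-7704 (1 and 12 counts) included. Carried by miR-7641 with 503 and 249 counts, the list's summed counts had a ratio of 0.766 (0.659 to 0.888), or 1.18 under upper-quartile scaling.

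Detection in a single library mostly concerned a few reads. Of 29 microRNAs listed only in co-culture, 21 had 1 count, and of 43 listed only in the alone library, 22 had 1 count. MiR-1973 was the exception, with 794 counts in co-culture and none listed alone, at least 378.7-fold higher against the floor of 3 counts. Its annotated hairpin (chromosome 4, 116299725 to 116299768, plus strand) lies in an exon of MTRNR2L13, a nuclear gene that resembles mitochondrial 16S rRNA, and shares 19 bases with that rRNA (MT-RNR2). MiR-193b-3p had 14 counts in co-culture only, at least 6.68-fold higher. MiR-455-5p had 9 counts, at least 4.29-fold higher, and miR-29a-5p 5 counts. In the alone library only, miR-191-3p had 16 counts, at least 3.73-fold lower in co-culture, and the next, miR-378a-5p, had 7. The bounds rest on the floor, and the exact intervals reach lower, to 307-fold for miR-1973, 4.75-fold for miR-193b-3p, 2.82-fold for miR-455-5p and 2.70-fold for miR-191-3p. Of the 855 counts only in co-culture, miR-1973 took 794, against 104 counts in all for entries found only alone.

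The authors' deposited table calls 49 of 190 shared microRNAs up, 49 down and 92 neutral, with up calls from a log2 ratio of 1.03 and neutral ones to 0.99. Of the calls held in the 188 rows analysed, 26 of 47 up and 18 of 49 down had a mean count under 10. In the authors' deposited table, which rests on 1 library per condition, the adjusted p was 0.0138 for miR-1973 and 0.477 for miR-181a-5p. It was 1 for the other 257 of 259 microRNAs with a value, including both microRNAs of the title.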

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

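The list medians and named microRNAs under upper-quartile scaling and the sum of miR-3184-5p with miR-423-3p were chosen after the data were seen, and the other alternatives before. Upper-quartile scaling turned the balance of the 2 directions. It gave 37 higher microRNAs and a median log2 ratio of 0.39, in place of 22 and −0.24, and the share of higher among all called was 62.7% against 41.5%. The cause was not tested. Upper-quartile scaling was computed over all 260 entries, with counts of 0 included. It therefore rests on 1 point of the ranked counts in each library, which has its own counting error. The other scalings, the authors' deposited ratios, a prior count of 5 and the restriction to shared microRNAs gave 21 to 24 higher and 30 or 31 lower. The count limits changed the numbers by changing how many microRNAs were classed. Without a limit 75 were higher and 92 lower of 260, and at a mean count of at least 50 there were 14 higher and 20 lower of 76, with a median of −0.32. Of the microRNAs listed only in co-culture, 6 had at least 4 counts and 2 at least 10. Of those listed only alone, the numbers were 7 and 1.

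Of 85 named microRNAs, 80 stayed within their counting interval under the trimmed mean of M values, 69 under the median of ratios and 73 with a prior count of 5. Upper-quartile scaling changed the sign of 13 and moved 11 across the 2-fold limit. With the prior count of 5, 14 crossed the 2-fold limit. Of these only miR-4454 had a mean count of at least 10, so the others were not among those classed above. The sign of 4 changed, and miR-374c-5p, which rests on 2 counts, went from below 0 to 0.031. MiR-3184-5p reversed to a log2 ratio of −1.52 when its counts were summed with those of miR-423-3p, as the sum is mostly miR-423-3p counts in the alone library. Of 17 list medians, 5 changed sign under at least 1 scaling. Without the count limit 8 moved beyond their counting interval and 3 changed sign, such as the inflammation-responsive list from −0.14 to 0.52, and the chromosome 14 cluster went from −1.34 to −0.22 and the blood and immune list from 1.52 to 0.41. About equal shares of the listed microRNAs, 49.8% alone and 50.2% in co-culture, had fewer than 10 counts, where counting intervals are widest.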

Other observations

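All tests below except that of equal naming of miR-3184-5p and miR-423-3p were chosen after the result was seen. Arms were compared for names that match 1 annotated hairpin only, which leaves out, among those with enough counts, let-7a and miR-181a. Both arms were listed for 60 such hairpins, and both reached a mean count of 10 for 12. Of these, 6 had arms with the same sign, and in 2, miR-181c and miR-3184, the arms differed by at least 2-fold in opposite directions. Under upper-quartile and median-of-ratios scaling let-7b joined them. Let-7b-5p had 526 counts alone and 674 in co-culture, and let-7b-3p 33 and 1. MiR-30e-5p had 398 and 187 counts, while miR-30e-3p had 6 and 38, 9.06-fold higher in co-culture (3.80 to 26.2). The median gap between arms was 1.79 on the log2 scale, against 2.52 for random pairings of these arms, and 10% of random pairings had a gap as small.

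The level of miR-3184-5p in co-culture ran opposite to that of miR-423-3p at the same place on the other strand. Equal naming of reads for both strands needs a ratio of miR-3184-5p to miR-423-3p counts within 1.5-fold of 1 in both libraries, and the ratio was 0.00534 alone and 6.36 in co-culture; the preset bound against it, under 0.1 in both, was met alone only, so its exclusion rests on both ratios lying outside that range, a reading made after the values were seen. A fixed share of misnamed reads is argued against for this arm too, since the share was 0.531% alone and 86.4% in co-culture. On the other arm miR-3184-3p had 1249 and 213 counts, and miR-423-5p was not among the entries analysed. The share named miR-3184-3p is 100% in both libraries only because an unlisted name was taken as 0. A fixed share could therefore not be examined there. Reads named for either strand at other loci decide nothing, as 4 of 7 other opposite-strand pairs, with the 2 hairpin copies of miR-103a taken once, had both members listed, 57.1% (25.05% to 84.18%) against 11.4% of all annotated hairpins, but with at most 2 counts for the lesser member. A naming that differed between the libraries could still account for the difference, although the partner of miR-103a-3p (408 and 383 counts) was not among the entries analysed, and a real switch in the cells was not tested.

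MiR-1973 was listed with 794 counts in co-culture and not at all alone. Its hairpin ends in 19 bases, ACCGTGCAAAGGTAGCATA (hairpin positions 26 to 44), that occur unchanged in mitochondrial 16S rRNA, while the longest such stretch in 213 other listed hairpins was 13. This falls 1 short of the 20 bases set as the limit. The stretch runs to the last base of the hairpin, so a longer match could only have come at its other end, where it stops at position 26. The test therefore decides neither for nor against an rRNA fragment. Since a read of those 19 bases would match both places, microRNA and rRNA fragment cannot be told apart from counts. More degraded RNA in co-culture stays open too, because the summed entries that resemble rRNA or tRNA had a ratio of 0.766 (0.659 to 0.888), carried by miR-7641, but of 1.18 under upper-quartile scaling, while miR-4454 had 8 counts alone and 13 in co-culture and miR-7704 had 1 and 12, a ratio of 17.2 (2.54 to 734). A response of the cells was not tested.

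The 12 microRNAs with the largest increases could in part come from the mouse cells, as many mature sequences are shared between mouse and human and would align to the human genome. The tested members of the adipocyte list had a median log2 ratio of −0.26 and those of the fibroblast list one of 0.77, both short of the 1 set for carry-over, but the second was 1.39 under upper-quartile scaling, and over all 10 listed adipocyte members the median was 0.34. MiR-143-3p, abundant in adipocytes, had 4 counts alone and 3 in co-culture, and miR-378a-3p, the most abundant tested adipocyte marker, had 1997 and 1654, whereas miR-193b-3p had 0 and 14, miR-365a-3p 4 and 12 and miR-148a-3p 0 and 1. All 4 tested adipocyte markers were also listed in the cancer cells alone, with 193 to 1997 counts. Against that background only a large carry-over would move their median to 1, so the median cannot decide the question. The membrane would hold back cells but not vesicles, so transfer and a response of the cancer cells cannot be told apart here.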
